A study of Homo sapiens and Mus musculus and Homo sapiens
Mus musculus with 10 samples.

How the data were processed

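Bulk libraries of HEK293T, GM12878 and NIH/3T3 cells and a single-cell library of mixed HEK293T and NIH/3T3 cells were analysed from the deposited gene count tables. Per the labels, the authors deposited raw counts per gene for each bulk library and raw counts per gene and barcode for the single-cell library, with no normalization. Per the submitters' processing notes the reads went through fastp, STAR, Picard and HTSeq on the builds hg38 and mm10. Versions, order and filters of these tools, the annotation release and the strand setting of the counting are not given in the sources used here. Of the single-cell entries 91.0% were even, so a read pair appears to enter as 2 counts. Samples were grouped by the cell line and the methanol percentage of their treatment labels, with 1 library per group.

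Reads without a gene, ambiguous and multiply aligned reads are listed beside the genes in the bulk tables and stayed out of library sizes and tests. Reads without a gene made up 80.2, 47.0 and 38.9% of counted reads in HEK293T at 30, 40 and 50% methanol, and 57.3, 66.5 and 83.0% in GM12878 at 40, 60 and 80%. In NIH/3T3 at 30, 40 and 50% they made up 58.5, 47.6 and 54.3%. Multiply aligned reads reached 28.9% in HEK293T at 50%. Of 61498 human gene identifiers 99.8% had a name in the name table supplied, and 94.8% had an entry in GENCODE release 29, which gave gene types, coordinates, exon lengths and GC content. None of the 55357 mouse identifiers had a name, so mouse genes are given by identifier and no mouse marker was used. Second copies of genes of the pseudoautosomal region (46) held no count and were left out. Depth ran from 567583 gene counts in GM12878 at 80% to 4976425 in HEK293T at 50%.

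The human bulk libraries were fitted with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) after filterByExpr with a minimum count of 10 and TMM scaling, by quasi-likelihood F tests with terms for the line and for methanol per 10 points, centred at 40%. The fit had 3 residual degrees of freedom, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Values after ± are the absolute log2 difference over the square root of F, which only approximates an SE. DESeq2 1.42.0 was the second tool. Genes were named by a rule set before the data were examined. In tested comparisons it took the 8 genes with the largest change in each direction among called genes with a mean of at least 20 CPM over the libraries of the fit, and up to 3 called members of each list by p. Clone-based names, numbered long intergenic RNAs, small RNAs and pseudogenes were passed over. Where fewer than 16 genes were called, the genes of smallest p filled up to 16 and are given as values. In comparisons of 1 library with 1, it took the 8 genes per direction whose counting interval lay farthest from no change, and the 3 members of highest mean CPM of each list. For single cells it took the cell type markers and the 3 most abundant genes of each class, and mouse genes were cut to 2 per direction. Not every gene that this rule names is reported here. A group with no count was set at a floor of 3 counts to give a lower bound of the ratio, and groups with 1 to 3 counts were given a ratio with its 95% conditional Poisson interval.

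The 20 gene lists fixed beforehand were mitochondrially encoded mRNAs, cytosolic ribosomal proteins, nuclear-retained long noncoding RNAs, replication-dependent histones, heat shock proteins, immediate early genes, unfolded protein and integrated stress response genes, S phase genes, G2/M genes, very long mRNAs, short nuclear-encoded respiratory chain mRNAs, glycolysis, cholesterol biosynthesis, proteasome subunits, B lymphocyte markers, EBV and NF-kB induced genes, HEK293-enriched and epithelial genes, fibroblast and extracellular matrix genes, erythroid and myeloid markers, and T and NK cell markers. They were tested with camera at a correlation of 0.01 and with an estimated correlation, and with fry. The 7 library measures were regressed on methanol within lines and tested by exact permutation within lines, with 216 assignments over 9 libraries and 36 over 6. Genes detected were counted after thinning to 567583 counts.

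Ratios within a line used genes with at least 100 counts over the pair, an offset of 0.5 counts and 95% counting intervals. Medians of lists were placed among 10000 random lists matched in 20 bins of mean expression, which gives a percentile and no p. Correlations of libraries used log2 of CPM with a pseudocount of 1. Barcodes of the mixture with at least 1000 counts were classed as human or mouse at 90% of counts on genes of that species and as mixed otherwise, and barcodes with at least 500 and fewer than 1000 counts served as background. No doublet caller was run. Barcodes with cells of both species fall in the mixed class, but those with more than 1 cell of a species stay in the human or mouse class and enter its medians, sums and covariation. Summed cells were compared with the 40% bulk library over shared identifiers. Single-cell steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

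The methods were tested on simulated data. With the dispersion of the 6 libraries, 6.5% of 200 genes with a line difference of log2 4 were recovered and 89.5% with log2 8. The methanol test recovered 56% of slopes of log2 2 per 10 points. Without HEK293T at 30%, GM12878 at 80% and the methanol term, 15% of line differences of log2 2 and 96% of log2 4 were recovered. Counting intervals held the true ratio in 96.35% of 2000 cases. The permutation test called 200 of 200 true slopes and 6 of 200 flat ones. Those true slopes were steep against their noise and simulated for 9 libraries only, so the 200 of 200 does not measure power for these data. Matched random lists placed 100 of 100 shifted and 6 of 100 unshifted lists outside the central 95%. Genes in that simulation varied independently and by counting error only. Its 6 of 100 therefore does not give the error rate for real lists, whose genes can vary together. Of 3000 simulated cells 0 were put in the wrong species and 140 were called mixed through background alone. The simulated cells of both species had the same depths and none shared a barcode, so these counts do not estimate the errors in the real mixture. Alternatives set beforehand changed the scaling, the filter, the test, the methanol coding, the libraries and the thresholds of the mixture. Those added after the data were seen left out 2 libraries with and without the methanol term, added the share of reads on genes, subtracted background from barcodes, compared the highest with the middle concentration and set cells against other bulk libraries.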

Results

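FLIT-seq reads long transcripts of single cells in droplets after the cells have been fixed in methanol, made permeable and reverse transcribed in place from an oligo-dT primer. The libraries address how well reverse transcription works in different cell lines and under different fixation conditions. HEK293T, a human embryonic kidney line, was fixed at 30, 40 and 50% methanol. GM12878, a human B-lymphoblastoid line immortalised with Epstein-Barr virus (EBV), was fixed at 40, 60 and 80% methanol. NIH/3T3, a mouse embryonic fibroblast line, was fixed at 30, 40 and 50% methanol. Each line and concentration was represented by 1 bulk library, which gave 9 bulk libraries. A further single-cell library held a mixture of HEK293T and NIH/3T3 cells fixed at 40%. The fixation protocol shared by all samples gives volumes that correspond to 80% methanol, whereas the treatment labels give 30 to 80%, and groups follow the labels here.

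Counts on genes were 751691, 2210057 and 4976425 in HEK293T at 30, 40 and 50% methanol, and 2644898, 1369963 and 567583 in GM12878 at 40, 60 and 80%. They were 2044040, 2409044 and 1567783 in NIH/3T3 at 30, 40 and 50%. The share of counted reads that fell on genes was 10.3% (exact 95% interval 10.249 to 10.293) in HEK293T at 30%. It was 38.4% (38.399 to 38.478) at 40% and 30.3% (30.239 to 30.283) at 50%. In GM12878 it was 30.7% (30.657 to 30.719) at 40%, 21.2% (21.203 to 21.266) at 60% and 8.22% (8.197 to 8.238) at 80%. In NIH/3T3 it lay between 24.5% and 28.1%. Intervals on shares and counts cover counting error only, because reads amplified from 1 molecule are not independent.

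Olfactory receptor genes, which are transcribed in olfactory neurons, took 891.3 CPM (counts scaled to the library total) in HEK293T at 30%, 45.7 CPM at 40% and 37.6 CPM at 50%, summed over 381 genes. In GM12878 the same genes took 127.0 CPM at 40%, 377.4 CPM at 60% and 1684.3 CPM at 80%. Keratin-associated protein genes, which are active in hair follicles, took 460.3 CPM in HEK293T at 30% and 11.8 CPM at 40%, and 119.8 CPM in GM12878 at 80% against 41.6 CPM at 60%. Mitochondrially encoded mRNAs, which code for subunits of the respiratory chain, took 7.28, 0.953 and 0.851% of gene counts in HEK293T at 30, 40 and 50%, and 18.4, 6.36 and 9.21% in GM12878 at 40, 60 and 80%. Cytosolic ribosomal protein mRNAs took 2.26, 19.7 and 27.0% in HEK293T and 6.53, 9.53 and 5.54% in GM12878. At an equal depth of 567583 counts, 37117 genes were detected in HEK293T at 30% against 18068 and 17849 at 40 and 50%. In GM12878 37932 were detected at 80% against 20657 and 25452 at 40 and 60%. NIH/3T3 gave 22915, 16789 and 20369 genes.

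**Figure D1:**
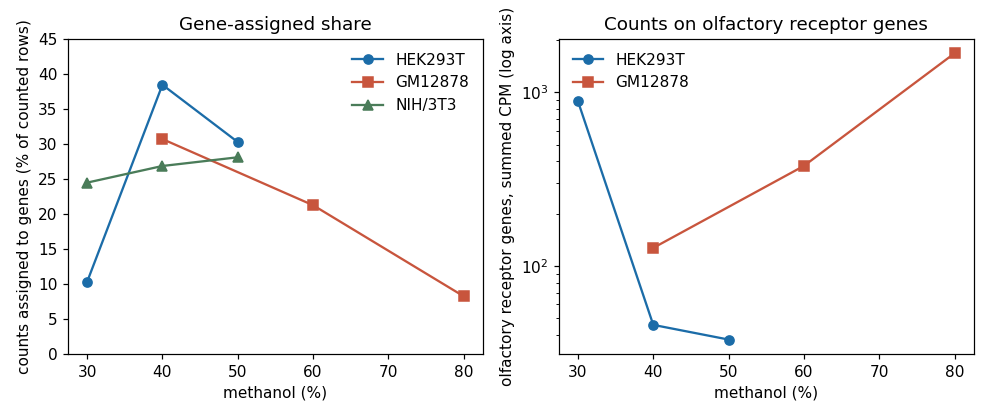
The left panel plots the share of counted reads assigned to genes (%) and the right panel the summed CPM of olfactory receptor genes (log axis) against methanol (%), with 1 point per bulk library and lines joining libraries of a cell line. The share is lowest in HEK293T at 30% (10.3%) and GM12878 at 80% (8.22%), the libraries in which olfactory receptor CPM is highest within their lines (891.3 and 1684.3).

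None of the 7 measures fixed for the libraries followed methanol in an exact two-sided permutation test of concentrations within lines, with p between 0.167 and 0.787 and an adjusted p of 0.787 for each. The mitochondrially encoded share had a slope of -2.49 percentage points per 10 points of methanol (permutation p = 0.167), which was -0.893 without GM12878 at 40%, -4.63 without GM12878 at 80% and -3.91 per rank of concentration. The ribosomal protein share had a slope of 2.28 (permutation p = 0.333), which was 0.194 without HEK293T at 30%, 0.796 without HEK293T at 50%, 5.18 without GM12878 at 40%, 6.93 without GM12878 at 80% and 5.93 per rank. Genes detected at equal depth had a slope of 1061 (permutation p = 0.704), which was -2836.5 without GM12878 at 80% and -1556 without GM12878 at 40%. The share of the 100 most abundant genes had a slope of -0.758 (permutation p = 0.787), and 3.30 without GM12878 at 40% or 2.12 without GM12878 at 80%. For nuclear-retained long noncoding RNAs the slope of 0.0149 (permutation p = 0.667) was -0.0170 without GM12878 at 40%, and for histone mRNAs the slope of -0.0026 (permutation p = 0.778) was 0.00266 without GM12878 at 80%. The mean log2 CPM of very long minus short respiratory chain mRNAs had a slope of -0.40 (permutation p = 0.389), and 0.07 without HEK293T at 30%. The smallest p that the design allows is 0.00926 for measures over 9 libraries and 0.0556 for measures over the 6 human libraries, so a measure over the human libraries alone could not reach 0.05.

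The comparison of the human lines asked which genes separated HEK293T from GM12878 at equal methanol. Genes of the B lymphocyte led on the GM12878 side: IGHM, the constant region of the immunoglobulin mu heavy chain, had 1287, 446.7 and 382.3 CPM at 40, 60 and 80% and no count in HEK293T. It was at least 2444-fold higher over the group against a floor of 3 counts. IGLC2, the constant region of a lambda light chain, had 1455 to 2873 CPM in GM12878 and 3 counts in HEK293T (ratio 6460, 95% counting interval 2210 to 31329). MS4A1, which encodes the B cell antigen CD20, had 1157 to 1535 CPM and 2 counts (ratio 5045, 1396 to 41664). On the HEK293T side, PITX1, a homeobox factor of limb and pituitary development, had 220.8, 558.8 and 975.6 CPM at 30, 40 and 50% and 0.378, 0 and 8.81 CPM in GM12878, with a log2 difference of 11.55 ± 2.23 (SE). PHLDA2, an imprinted gene that restrains placental growth, had 6.65 to 76.5 CPM in HEK293T and no count in GM12878, at least 85.1-fold higher. EEF1A2, a translation elongation factor of neurons and muscle, reached 1458 CPM in HEK293T at 50% and 0 to 30.0 CPM in GM12878.

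In all, 436 of 14464 genes differed between the lines by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 268 higher and 168 lower in HEK293T, and 3449 had an unadjusted p under 0.05. Further genes higher in HEK293T were the homeobox gene HOXB9 (log2 difference 12.54 ± 1.53, edgeR adjusted p = 0.0366), the membrane protein gene CMTM8 (12.15 ± 1.47), the forkhead gene FOXC1 (11.11 ± 1.78), the HOXA10 antisense transcript HOXA10-AS (1 count in GM12878) and BEX3 (1 count in GM12878, ratio 2870, 514.9 to 113388). In GM12878 at 40, 60 and 80%, HOXB9 and CMTM8 each had 0, 0 and 7.05 CPM and FOXC1 0, 1.46 and 3.52 CPM. Their fitted differences rest on these values near 0 and on the methanol term, so their sizes are uncertain. Fitted differences of other genes near 0 in a line have the same limit. HOXA10-AS lies across from HOXA10, and its level is uncertain because a strand setting of the counting was not given in the sources used here. Further genes higher in GM12878 were SRGN, the proteoglycan serglycin of blood cell granules (785 to 1191 CPM against 1 count, ratio 7364, 1321 to 290931), the Toll-like receptor gene TLR10 (at least 392.7-fold), the immunoproteasome subunit PSMB8 (at least 273.7-fold), the G protein regulator RGS1 (at least 397.9-fold) and DAPP1, an adaptor of B cell receptor signalling (at least 236.7-fold). On hg38 and the GENCODE 29 annotation, IGHM (ENSG00000211899.10) spans chromosome 14 from 105851705 to 105856218, MS4A1 (ENSG00000156738.18) chromosome 11 from 60455752 to 60470760, PITX1 (ENSG00000069011.16) chromosome 5 from 135027735 to 135034813, and PHLDA2 (ENSG00000181649.8) chromosome 11 from 2928273 to 2929455. These p-values measure only the spread between these samples. Across 12075 genes, CPM followed GC content with Spearman coefficients of 0.66, 0.09 and 0.36 in HEK293T at 30, 40 and 50%. In GM12878 at 40, 60 and 80% the coefficients were -0.37, -0.43 and -0.22. The numbers of genes called between the lines, in this and the other fits, were not corrected for GC content. How many of those genes go with it was not tested. DESeq2 called 2413 genes, the edgeR fit without a methanol term 1221 and without a filter on low counts 807. The count was 7242 without HEK293T at 30%, 0 without HEK293T at 50%, 0 without GM12878 at 40%, 158 without GM12878 at 60% and 792 without GM12878 at 80%.

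**Figure D2:**
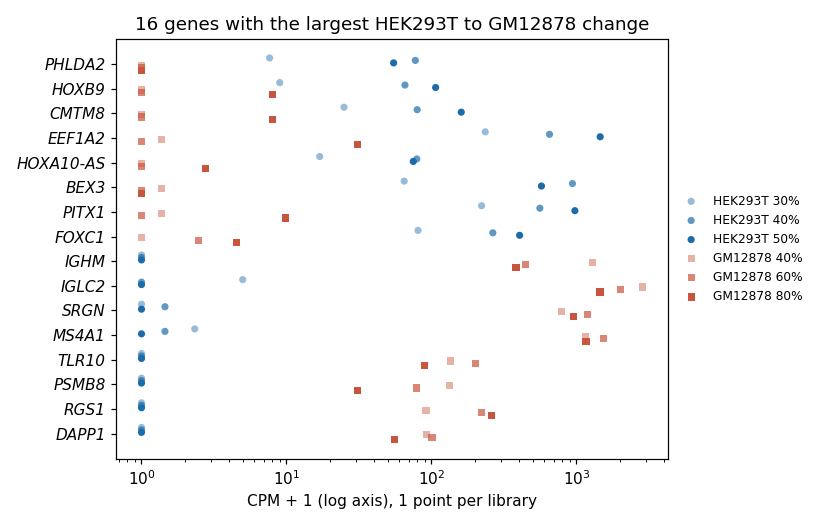
CPM plus 1 (log axis) of the genes with the largest differences between lines is plotted for each of the 3 HEK293T and 3 GM12878 libraries, 1 point per library. HEK293T points of IGHM lie at 0 in all 3 libraries and GM12878 points between 382.3 and 1287 CPM, while PITX1 lies at 220.8 CPM or more in HEK293T and at 8.81 CPM or less in GM12878.

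Among 40 B lymphocyte markers with enough counts, 10 were lower in HEK293T over all genes tested and 29 when adjusted over the list alone. They included PTPRC, the CD45 phosphatase of blood cells (1 count in HEK293T, ratio 1119, 200.1 to 44268), the tetraspanin CD53 (log2 difference -8.05 ± 1.22) and the antigen presentation gene HLA-DQA1 (-5.83 ± 0.92). Among 21 genes induced by EBV latency proteins or NF-kB, 4 were lower in HEK293T and 14 adjusted over the list alone. These held the apoptosis inhibitor BCL2A1 (2 counts in HEK293T, ratio 789.9, 218.0 to 6533), the chemokine CCL3 (1 count, ratio 240.8, 42.5 to 9578) and the microRNA host MIR155HG (-8.02 ± 1.52). Among 32 HEK293-enriched and epithelial genes, 10 were higher in HEK293T and 17 were higher and 1 lower adjusted over the list alone. They included HOXA10 (8.59 ± 1.25) and the keratin gene KRT18 (7.35 ± 1.24). Single members of other lists also passed edgeR's test. JUN, an AP-1 transcription factor, was higher in HEK293T (6.76 ± 1.43, edgeR adjusted p = 0.0487). Lower in HEK293T were SEL1L of protein quality control in the endoplasmic reticulum (-4.01 ± 0.87), the mitotic gene CDCA2 (-4.34 ± 0.94), the lipid transfer gene VPS13C (-3.62 ± 0.75), the sterol carrier STARD4 (-4.39 ± 0.86) and the T cell receptor constant gene TRBC2, which was at least 76.8-fold lower.

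Counts per list were 1 of 27 immediate early genes (adjusted over the list alone 3 higher and 2 lower), 1 of 25 unfolded protein response genes (list alone 1 lower), 1 of 52 G2/M genes (list alone 0), 1 of 60 very long mRNAs (list alone 7 lower), 1 of 23 cholesterol biosynthesis genes (list alone 1 lower) and 1 of 4 T and NK cell markers (list alone 1 higher and 2 lower). No member passed over all genes tested among 10 histone genes (list alone 1 higher and 1 lower), 33 fibroblast genes (list alone 7 higher and 2 lower), 13 mitochondrially encoded mRNAs (list alone 1 lower), 76 ribosomal protein genes, 12 nuclear-retained long noncoding RNAs, 18 heat shock genes, 42 S phase genes, 44 short respiratory chain genes, 20 glycolysis genes, 30 proteasome genes and 3 erythroid and myeloid markers. Of the 20 lists, camera with a preset correlation called 7, namely the B lymphocyte (adjusted p = 1.44e-20), EBV and NF-kB, very long, mitochondrially encoded, S phase and G2/M lists as lower and the HEK293-enriched list as higher in HEK293T. None of these calls held with an estimated correlation, where adjusted p = 0.219 for the B lymphocyte list with an estimated correlation, 0.217 for the EBV and NF-kB, HEK293-enriched and very long lists, 0.504 for the mitochondrially encoded list and 0.980 for both cell cycle lists. By fry, the B lymphocyte, EBV and NF-kB, HEK293-enriched and very long lists each had an adjusted p of 0.0219. Without HEK293T at 30% and GM12878 at 80%, an alternative added after the data were seen, 5925 of 13769 genes differed by edgeR. That fit left 1 residual degree of freedom, so its count is uncertain. With the methanol term also left out, 6676 differed, 3278 higher and 3398 lower, among them all 436 genes with the same sign. In that fit without a methanol term 37 of 39 B lymphocyte markers, 16 of 21 EBV and NF-kB genes and all 13 mitochondrially encoded mRNAs were lower in HEK293T. Of 60 very long mRNAs 41 were lower and 1 higher, and of 34 HEK293-enriched genes 22 were higher and 4 lower. Higher were 33 of 77 ribosomal protein genes and 21 of 44 short respiratory chain genes. Some other lists went both ways, with 23 lower and 7 higher of 52 G2/M genes and 14 lower and 2 higher of 44 S phase genes. Of 26 immediate early genes 6 were lower and 8 higher, and of 26 unfolded protein response genes 7 were lower and 5 higher.

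The methanol trend asked which genes moved with concentration in both human lines. The genes with the smallest p included HOXB9, with 7.98, 64.7 and 105.9 CPM in HEK293T at 30, 40 and 50% and 0, 0 and 7.05 CPM in GM12878 at 40, 60 and 80%, and CMTM8, with 23.9, 78.7 and 159.6 CPM and 0, 0 and 7.05 CPM. MAF, a basic leucine zipper factor, had 22.6, 20.8 and 84.2 CPM in HEK293T and 0, 0.73 and 8.81 CPM in GM12878. PPARG, the nuclear receptor of fat cell differentiation, had 31.9, 24.4 and 60.3 CPM and 0.378, 11.7 and 37.0 CPM. GM12878 at 80% had 567583 gene counts, so the values of HOXB9, CMTM8 and MAF there rest on few counts. Olfactory receptor genes rose over the same GM12878 libraries, with 127.0, 377.4 and 1684.3 CPM. A rise of these genes in GM12878 cannot be told apart from that rise. No gene passed edgeR's test (smallest adjusted p = 1), 262 of 14464 had an unadjusted p under 0.05, of which 257 had a positive slope, and DESeq2 called 0. Without HEK293T at 30%, edgeR called 624 genes, among them 15 of the 16 genes of smallest p. No gene had a different slope in the 2 lines by edgeR's test of the difference, and 3218 had an unadjusted p under 0.05 there. With a preset correlation, camera called 9 of the 20 lists, and with an estimated correlation none, with a smallest adjusted p of 0.261 for the mitochondrially encoded, B lymphocyte, EBV and NF-kB, very long and HEK293-enriched lists with an estimated correlation. In simulated counts with the spread of these libraries, 0% of genes with a true slope of log2 1 per 10 points and 56% with log2 2 were recovered.

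Within HEK293T, ribosomal protein mRNAs were far more abundant at 50% than at 30% methanol, with a median log2 ratio of 4.77 over 75 genes, all 75 above 0 (percentile 100 among 10000 random lists matched on mean expression). RPS6, a component of the small ribosomal subunit, had 3953 CPM against 15.96 CPM, a 237.8-fold ratio (141.7 to 479.4), RPL5 of the large subunit 257.1-fold (127.9 to 759.0) and the elongation factor EEF1A1 174.9-fold (117.1 to 289.4). Short respiratory chain mRNAs (median log2 3.21, percentile 100), proteasome subunits (2.48, percentile 100), heat shock genes (2.40, percentile 99.7), glycolysis genes (2.63, percentile 97.9), S phase genes (1.66, percentile 99.9) and G2/M genes (1.58, percentile 99.98) were also higher at 50%. GAPDH of glycolysis had 5811 against 93.1 CPM and the replication helicase subunit MCM7 1459 against 65.2 CPM. Mitochondrially encoded mRNAs were lower at 50% (median log2 -3.92, percentile 0, and -1.35 relative to the TMM scale), with MT-CO1 of cytochrome oxidase at 797 against 15267 CPM. Mitochondrial tRNAs MT-TE, MT-TY and MT-TF had 8.04, 11.5 and 15.3 CPM at 50% against 1200.0, 1299.7 and 1258.5 CPM at 30%. Very long mRNAs were lower at 50% by CPM (median log2 -1.82, percentile 0) but higher by 0.76 relative to the TMM scale, which lay at a log2 ratio of -2.58. Other lower genes included CHD5, a chromatin remodeller of neurons (2.21 against 251.4 CPM), and the transferrin receptor gene TFR2 of hepatocytes (1.00 against 137.0 CPM). Of 6869 genes with 100 or more counts, the counting interval placed 1632 over 2-fold higher and 1641 over 2-fold lower by CPM. Their median log2 ratio was 0.18 by CPM, above the TMM scale at -2.58, so relative to that scale most genes were higher. Across genes the correlation of log CPM was 0.14 between 30 and 50% and -0.10 between 30 and 40%. These differences go along with a share of reads on genes of 30.3% at 50% against 10.3% at 30%, and with olfactory receptor counts of 37.6 against 891.3 CPM. If the olfactory receptor density held over all exons, it would make up 13.85% of gene counts at 30% and 0.580% at 50%. At 30% that density was 0.745 counts per kb, against 4.36, 4.28 and 1.31 for keratin-associated protein, taste receptor and beta defensin genes. Over identifiers shared with the mixture, the median per gene at 30% was 0.194 counts per kb for olfactory receptors and 1.38 for keratin-associated proteins. It was 0 for type 2 taste receptors and for beta defensins. Family means lay above these medians, so the 13.85% may be too low or too high. The ratios were not corrected for such counts. There is 1 library per concentration, so these ratios have no replicate check and compare libraries, not conditions.

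Between HEK293T at 50% and at 40%, which correlated across genes with r = 0.84, the heat shock list had a median log2 ratio of -1.26 (percentile 0.00), with HSPA8, a constitutive chaperone, at 424.0 against 1543 CPM and HSP90AA1 at 325.7 against 953.4 CPM. Immediate early genes (-1.14, percentile 0.09), unfolded protein response genes (-1.05, percentile 0.02), S phase genes (-0.89, percentile 0.04) and G2/M genes (-0.88, percentile 0.01) were also lower at 50%, and relative to the TMM scale, which lay at -0.47, these 5 medians ran from -0.79 to -0.41. Other lists were lower as well, with medians of -1.27 for nuclear-retained long noncoding RNAs (percentile 0.80) and -0.56 for mitochondrially encoded mRNAs (percentile 1.56). Relative to the TMM scale these 2 medians were -0.80 and -0.09. Histone mRNAs, which lack a poly(A) tail in cycling cells, had a median of 0.78 over 4 genes (percentile 99.1). APOE, the lipid carrier apolipoprotein E, was 11.3-fold higher at 50% (9.40 to 13.9) and SPINT2, a serine protease inhibitor, 9.77-fold higher (7.53 to 13.1). CGA, the common subunit of glycoprotein hormones, had 2 counts at 50% and 215 at 40% (log2 ratio -7.60, -10.97 to -6.05), HAND1, a factor of heart and placenta development, 2 and 192 (-7.44, -10.81 to -5.88), and the growth factor gene BMP2 2 and 158 (-7.16, -10.53 to -5.60).

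Within GM12878, cell cycle genes were lower at 80% than at 40% methanol, with a median log2 ratio of -0.93 for S phase genes (percentile 0.00) and -1.02 for G2/M genes (percentile 0.00). The topoisomerase gene TOP2A had 176.2 against 614.8 CPM and the proliferation marker MKI67 163.9 against 590.2 CPM. Heat shock genes (-0.86, percentile 1.19) and proteasome subunits (-0.71, percentile 0.32) were lower as well, with the chaperone gene HSP90AB1 at 396.4 against 2144 CPM. Mitochondrially encoded mRNAs had a median of -1.12 (percentile 1.04), with MT-ND5 of complex I at 8903 against 31963 CPM. Nuclear-retained long noncoding RNAs had a median of 1.05 (percentile 100) by CPM and of -0.46 relative to the TMM scale, which lay at 1.51. Higher genes by the fixed rule included MUC16, the epithelial mucin CA-125 (17.3-fold, 11.5 to 27.4), and CACNA1A, a neuronal calcium channel (10.1-fold, 7.18 to 14.7). Between 60 and 40%, ribosomal protein mRNAs (0.63, percentile 100) and short respiratory chain mRNAs (0.75, percentile 100) were higher, also relative to the TMM scale at 0.51 (0.12 and 0.25), and mitochondrially encoded mRNAs lower (-1.57, percentile 0.00), with MT-CO2 at 4126 against 13738 CPM. Between 80 and 40% the ribosomal protein and short respiratory chain medians were -0.13 (percentile 100) and -0.16 (percentile 80.6), and -1.64 and -1.67 relative to the TMM scale. Of 5410 genes, 61 lay over 2-fold higher and 152 over 2-fold lower at 80% than at 40% by CPM. Their median log2 ratio was -0.20 by CPM, below the TMM scale at 1.51, so relative to that scale most genes were lower. These differences go along with a share of reads on genes of 8.22% at 80% against 30.7% at 40%, and with olfactory receptor counts of 1684.3 against 127.0 CPM. If the density on olfactory receptor genes held over all exons, it would make up 26.2% of gene counts at 80% and 1.97% at 40%, and the ratios were not corrected for it.

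In NIH/3T3, 3 of 4903 genes lay over 2-fold higher and 18 over 2-fold lower at 50% than at 30% methanol. At 40 against 30% they were 30 higher and 27 lower of 6212, and at 50 against 40%, a pair added after the data were seen, 12 higher and 81 lower of 5738. The mouse files pair no gene names with identifiers. ENSMUSG00000102349.2 was 3.85-fold higher (3.22 to 4.64) and ENSMUSG00000092341.4 3.04-fold higher (2.68 to 3.47), while ENSMUSG00000064371.1 had 3.83 against 110.6 CPM and ENSMUSG00000064372.1 19.8 against 342.5 CPM. The 3 NIH/3T3 libraries correlated across genes with r of 0.937 to 0.961, the 3 GM12878 libraries with r of 0.785 to 0.916 and the 3 HEK293T libraries with r of -0.10 to 0.84. Genes are not independent replicates in these correlations.

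The mixture asked whether droplets hold transcripts of 1 species. Of 10766 barcodes with 1000 or more counts, 2697 had at least 90% of counts on human genes (25.1%, exact 95% interval 24.2 to 25.9), 1111 had at most 10% (10.3%, 9.75 to 10.9) and 6958 were mixed (64.6%, 63.7 to 65.5). The mixed share was 37.1% of barcodes with at least 2000 counts, 19.1% with at least 5000 and 13.5% above the knee of the ranked barcodes at 10033 counts. Human-class barcodes had a median of 11809 counts and 2433 genes, and mouse-class barcodes 6939 counts and 2286 genes. Thinned to 2000 counts, the medians were 865 human-class and 1273 mouse-class genes, with 42 and 26 shallower barcodes left out. Among 39656 background barcodes with at least 500 and fewer than 1000 counts, 49.9% of counts were human.

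HEK293T markers were counted in more human-class barcodes than other barcodes, which hold far fewer human counts. CKB, brain-type creatine kinase, was counted in 50.9% of human-class barcodes (49.0 to 52.8), 9.99% of mouse-class barcodes (8.29 to 11.9) and 8.47% of background barcodes. Per human count its order was the opposite, with 144.1 CPM in the human class, 538.5 CPM in the mouse class and 668.4 CPM in background. Per human count 9 of the 10 HEK293T markers were lower in the human class than in background, among them KRT8 (20.3 against 36.4 CPM), STMN1 (15.8 against 66.8) and DLK1 (17.8 against 45.7), and IGF2BP1 was the exception. This RNA-binding protein gene was counted in 30.0, 0.450 and 0.545%, with 68.4, 19.4 and 46.6 CPM of human counts. These CPM are over all human counts, and mitochondrial genes took 49.5% of those in the human class. That share was not computed for background. A lower CPM in the human class therefore does not show a lower level among nuclear-encoded counts. The tubulin gene TUBB2B was counted in 14.1, 0.540 and 0.424% and the keratin gene KRT8 in 12.013, 0.630 and 0.305%. The other markers KRT18, GPC3, LIN28B, DLK1, STMN1 and NEFM lay between 1.34 and 11.9% of human-class barcodes. Markers of B lymphocytes, a cell type outside this mixture, were counted in 3.19% (CD79A) to 9.34% (CD74) of human-class barcodes for 9 of the 10 genes, against 0.0900 to 0.810% of mouse-class barcodes, and HLA-DRA in 0.185 and 0.180%. CD74, the class II invariant chain, had 15.6 CPM of human counts in the human class and 34.2 CPM in background. The 3 most abundant human genes were the mitochondrial tRNAs MT-TL2 (7.04% of human counts) and MT-TR (6.95%) and MT-CO1 (6.41%), and the most abundant mouse gene was ENSMUSG00000064367.1 (3.36%).

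**Figure D3:**
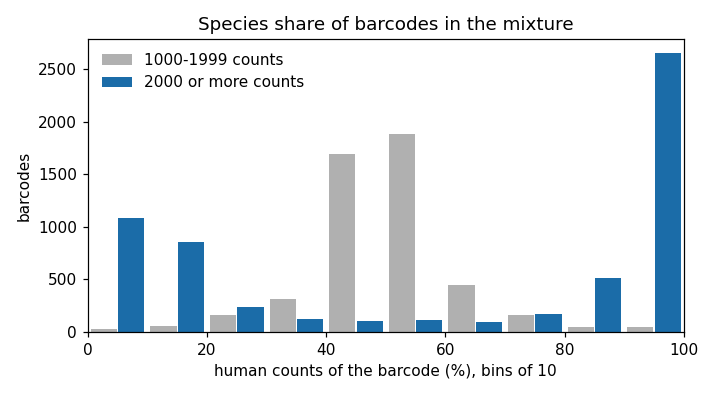
Barcodes are counted in bins of 10 percentage points of their human counts (%), separately for barcodes below 2000 counts and for those with 2000 or more. Barcodes below 2000 counts pile up near equal shares of both species (4756 of 4824 were mixed), and barcodes with 2000 or more counts lie mostly near 0 or 100%.

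The summed human-class cells were set against the HEK293T bulk library at the same 40% methanol, over gene identifiers listed in both with 100 or more counts in sum. Mitochondrial tRNAs took 37.2% of human counts in the cells and 0.0148% of the bulk counts. MT-TL2 had 70391 CPM in cells and no count in bulk, at least 50335-fold higher, and MT-TR 69533 CPM and 2 counts (log2 ratio 15.86, 14.33 to 19.23). How reads on such short neighbouring genes were assigned in each file is not given in the sources used here. The 3 mitochondrially encoded mRNAs compared were also higher in cells (median log2 5.79, percentile 99.9), and the other 10 were not analysed here. The mitochondrial shares given for the cells leave those 10 mRNAs out and are therefore partial. Ribosomal protein mRNAs had a median log2 ratio of -6.48 (percentile 0.00), with RPS2 of the small subunit at 130.9 against 22659 CPM. Short respiratory chain mRNAs had a median of -5.51 (percentile 0.00), with COX5A of cytochrome oxidase at 6.55 against 1130 CPM. Proteasome subunits had a median of -3.95 (percentile 0.50), very long mRNAs 1.61 (percentile 100), with the DNA repair kinase PRKDC at 545.6 against 152.9 CPM. Nuclear-retained long noncoding RNAs had a median of 0.17 (percentile 98.4) and histones 0.23 (percentile 1.09). These were the 7 of 20 lists outside the central 95% of random lists, and the medians of the other 6 kept their signs when mitochondrially encoded genes were removed before scaling, which moved log2 ratios by 0.98.

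Across 27036 human genes the log CPM of cells and bulk correlated with r = 0.461, and across 19317 mouse genes of the mouse class and NIH/3T3 at 40% with r = 0.0869. Against the other bulk libraries, an alternative added after the data were seen, r was 0.538 for HEK293T at 30%, 0.469 for HEK293T at 50% and 0.463, 0.452 and 0.527 for GM12878 at 40, 60 and 80%, and 0.154 and 0.140 for NIH/3T3 at 30 and 50%, so the 40% library of the own line was not the closest. Counts of 19481 protein-coding genes followed exon length with a Spearman coefficient of 0.68 in the cells and 0.30 in bulk, while over compared genes of all types the ratio of cells over bulk had -0.222. Over a smaller set of 12075 genes the same bulk library had -0.231, so the sign in bulk depends on the genes taken. Genes with no count in bulk had a density of 72.9 counts per kb in the cells, 58.97% of the density over all protein-coding genes (123.7 per kb), and olfactory receptor genes 79.7 per kb. In single cells most counts are even (91.0% of entries), so a fragment may enter as 2 counts and counting intervals on single-cell sums are too narrow. In the mouse class ENSMUSG00000064361.1 was at least 19982-fold higher than in NIH/3T3 at 40%. With 1 library on each side, no test was made.

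**Figure D4:**
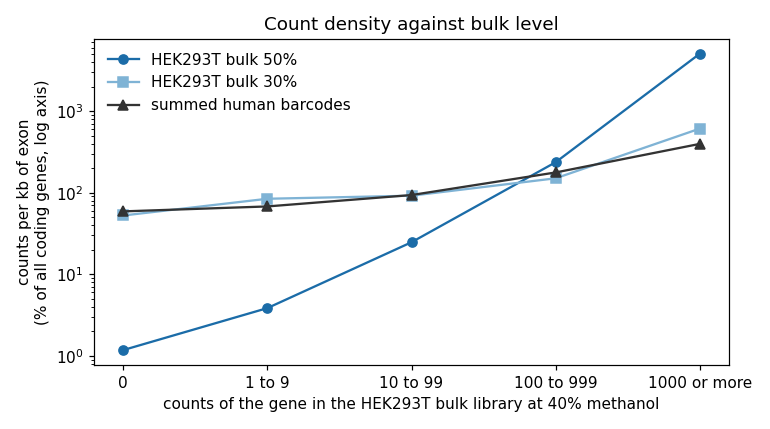
Counts per kb of exon, as a percentage of the density over all protein-coding genes (log axis), are plotted for genes grouped by their counts in the HEK293T bulk library at 40% methanol, with lines for HEK293T bulk at 50%, HEK293T bulk at 30% and the summed human-class barcodes. Genes with no count at 40% reach 1.18% at 50% methanol, 52.5% at 30% and 58.97% in the summed barcodes.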

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

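Every test of an explanation in this part was chosen after the results were seen.

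The share of counted reads on genes moved in opposite directions with methanol in the human lines, by 19.99 percentage points from 30 to 50% in HEK293T and by -22.47 from 40 to 80% in GM12878, and this difference between the lines was not tested. Olfactory receptor CPM also moved in opposite directions, by -853.7 in HEK293T and by 1557.3 in GM12878 over the same ranges, and this was not tested either. Reads without a gene, which no comparison used, were 80.15% of counted reads in HEK293T at 30% and 82.98% in GM12878 at 80%. Barcodes outside the human and mouse classes held 53.4% of the counts of the mixture. Of these barcodes, only the background barcodes entered comparisons of expression, for markers and count densities.

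Counts on silent gene families such as olfactory receptors and on markers of other cell types were high per gene count in HEK293T at 30% and GM12878 at 80%, which had the fewest gene counts of their lines. Against the library of the line with more gene counts and more counted reads, the silent families had 1212 counts in HEK293T at 30%, 3.156 times as many (95% counting interval 2.81 to 3.55), and 1103 in GM12878 at 80%, 2.664 times (2.38 to 2.99), which argues against depth for these families, while earlier forms of the test gave 1.817 in GM12878 at 80% against the 607 counts at 60%, and 2.05 and 1.49 for genes at equal depth, the latter just under its limit of 1.5. T and NK cell and erythroid and myeloid markers had 515 counts in HEK293T at 30%, 2.845 times as many (2.40 to 3.39), against depth, but 247 in GM12878 at 80%, 0.748 times (0.632 to 0.885) where gene counts were 0.215 times, so depth cannot be told apart there because these counts were fewer and yet above that share. Genes with no count in HEK293T at 40% had 52.5% of the count density of all protein-coding genes at 30%, which is consistent with reads that do not follow expression, such as reads primed on genomic DNA, while reads spread evenly per kb would give similar densities on 4 silent gene families, whose highest over lowest density was 1.505 in GM12878 at 80%, in line with it, but 5.855 in HEK293T at 30%, against it. Material of GM12878 in HEK293T at 30% would need a share of 14.996% to explain the B lymphocyte markers, and the 20 most abundant GM12878 transcripts give 1.84% (1.63 to 2.06), too low for it, while expression by HEK293T itself was not tested.

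Summed human-class cells had far fewer ribosomal protein counts and more mitochondrial tRNA counts than HEK293T bulk at the same methanol. Genes with no count in bulk reached 58.97% of the density of all protein-coding genes in the cells, which is consistent with reads that do not follow expression. Free material shared by all barcodes could bring 6.24% of the olfactory receptor counts of the human class. This lies below the 20% under which this explanation was set aside, for those counts only. It assumes that a human-class barcode takes up no more free material than a background barcode holds. Background barcodes had a similar profile. Genes with no count in bulk had 64.6% and olfactory receptor genes 73.6% of their density over all protein-coding genes, against 58.97 and 64.5% in the cells. A change of expression between the cells of the mixture and of the bulk library could not be tested with 1 library on each side.

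Barcodes with counts of both species may hold free material or cells of both species. With barcodes of at least 2000 counts, at least 80% of them on 1 species, in 4 groups by own counts, counts of the other species were at most 1.335 times as high in the top as in the bottom group, against 4.98 times for own counts in human and 3.62 times in mouse barcodes, which is in line with free material. After subtraction of the background 12.534% of barcodes with at least 5000 counts were still mixed, which is in line with cells of both species in a barcode. Both tests fit, and the share owed to each was not estimated.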

How the results depend on the processing

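Alternatives were set before the data were examined unless said otherwise. No paired analysis was possible because the labels give no replicate numbers and each group has 1 library. The planned fit of all 9 libraries was not run, since mouse genes had no names to join. The 436 genes between the lines became 2413 by DESeq2, 807 without a filter and 1221 without a methanol term, 5925 without HEK293T at 30% and GM12878 at 80%, and 6676 without these libraries and the methanol term, both chosen after seeing the data. With a library left out they ran from 0 to 7242. The methanol trend called 0 genes in all settings but 1, with a range of 0 to 624 over libraries left out. Of the lists, 7 called by camera for the line became 0 with an estimated correlation and 4 by fry, and 9 for methanol became 0 with an estimated correlation and 0 by fry.

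With concentrations as ranks, the slope of genes at equal depth was -756.5 and that of the share of the 100 most abundant genes 1.30, and the slope of genes without thinning was -66.6. With a library left out, slopes ran from -2836.5 to 3037.6 for genes at equal depth, from -2.68 to 3.30 for the 100 most abundant genes, from -0.0170 to 0.0220 for nuclear-retained long noncoding RNAs, from -0.00774 to 0.00266 for histones and from -1.30 to 0.0655 for very long minus short mRNAs. The share of reads on genes, a measure added after seeing the data, had a slope of -1.78 by percent (permutation p = 0.620), 0.191 by rank and -4.32 to 2.36 with a library left out.

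The mixed share of barcodes was 92.3, 37.1 and 19.1% at 500, 2000 and 5000 counts, 13.5% at the knee, and 51.0 and 81.9% at a purity of 80 and 95%. After subtraction of background, chosen after seeing the data, it was 16.8% at 2000 and 12.5% at 5000 counts. The correlation of cells with bulk was 0.614 and 0.541 with a minimum of 10 and 50 counts for human genes, 0.466 and 0.287 for mouse genes, and 0.0497 for mouse cells of at least 5000 counts. For all these changes the cause was not tested. None of the 31 genes named for the line or the 16 named for methanol changed direction. Both sets were picked from these same libraries by their change or their p, so a kept direction is no independent check. These alternatives did not cover the genes named within lines or between cells and bulk. Of the tested values of single genes, 497 kept their side of the threshold, 97 lost it and 15 gained it. The 31 genes compared at 40% alone, with no test, kept their direction, and 6 counts of human or mouse barcodes moved. Leaving out a library leaves 2 residual degrees of freedom, and shallow libraries limit genes of few counts.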

Other observations

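All tests and values in this part were chosen after the results were seen.

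Cell cycle genes and most other lists varied together more than most matched random lists between human-class barcodes. In 2448 barcodes thinned to 5000 counts, the sum of S phase genes, which act in DNA replication, had a variance 2.64 times the summed variances of its genes, against a highest of 2.03 in 1000 random lists matched on mean and bulk level, and the sum of G2/M genes 2.92 against 1.96. Very long mRNAs had 3.34 against 2.40, heat shock genes 1.91 against 1.87, immediate early genes 1.46 against 1.38 and histones 1.17 against 1.166. Ribosomal protein genes had 1.80 (percentile 8.1) and HEK293-enriched genes 1.28 (percentile 28.3). Markers of cell types outside the mixture also ranked high, with B lymphocyte markers at 1.39 (percentile 98.4), EBV and NF-kB genes at 1.22 (98.1) and T and NK cell markers at 1.16 (93.7), but erythroid and myeloid markers at 1.08 (63.0). Percentiles were 99.6 for unfolded protein response and short respiratory chain genes, 98.6 for nuclear-retained long noncoding RNAs, 98.0 for glycolysis, 91.7 for cholesterol biosynthesis, 69.3 for proteasome subunits and 21 for fibroblast genes. The matching on bulk level was added after a first run with matching on the mean alone and fewer random lists. Counts were divided by 2 after thinning, for the pairing of reads. No p is given, since barcodes of 1 library are not replicates.

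In 4 chosen pairs of genes on opposite strands, counts were close in some and far apart in others. TUBA1B, an alpha tubulin, had 7114 and TUBA1B-AS1 6330 counts in HEK293T at 40%, and RPL30 of the large ribosomal subunit 4159 and RPL30-AS1 3467, but 10 and 2 at 30%. MIF, a cytokine gene, had 0 counts in all 6 human bulk libraries while MIF-AS1 had 5472 in HEK293T at 40%, and in the summed human-class cells MIF had 323 and MIF-AS1 7. TUBA1B had 2825 and TUBA1B-AS1 227 counts in those cells. The strand setting of the counting is not given in the sources used here.

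As many or more genes separated the lines in 1 of the 10 splits of the 6 human libraries into groups of 3, the real one with 436, and the highest other split called 0. Of 18 orderings of methanol within lines, 7 gave as many genes as the real 262 at an unadjusted p under 0.05, with a highest other of 2306. With so few splits and orderings a share under 0.05 could not be reached (smallest 0.1 and 0.0556).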
